A study of Mus musculus with 12 samples.

How the data were processed

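The samples were 12 polyA RNA libraries from N2a cells, a mouse neuroblastoma line, in which a Flp-In site carried a doxycycline-inducible, FLAG-tagged Sap30bp cDNA. In one line this cDNA lacked exon 3 of Sap30bp (the exon-3-lacking line) and in the other it held exon 3 (the exon-3-containing line). Each line was studied with a non-targeting siRNA (control), with an siRNA against Sap30bp (knockdown), and with that siRNA plus doxycycline (rescue), which makes 6 groups with 2 biological replicates each. Per the labels, medium with or without doxycycline was given 24 hours after transfection, cells were harvested at 72 hours, and stranded libraries were made from 1000 ng of RNA with a mean insert of 540 nt. No group received the control siRNA together with doxycycline, so doxycycline and the induced isoform came together in every rescue group, and isoform and line were one and the same factor.

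The authors provided a vast-tools inclusion table on mm9 that gives, per event and library, the percent of transcripts that include an exon, use a splice site or retain an intron (percent spliced in, PSI). The version of vast-tools and the coverage rule behind missing values are not given in the sources used here. The authors' deposited table of gene expression holds 1 RPKM value per group, so replicates were combined before deposit, and for each of their comparisons a log2 fold change, a p-value and an FDR. Per the submitters' processing notes, Salmon 0.14.1 and edgeR were used upstream of that table. Recomputing Benjamini-Hochberg values from the deposited p-values differed from the deposited FDR by at most 0.00055. A table of the authors' differential splicing events lists 2175 events with a change in percentage points and a call per comparison. How those calls were made is not given in the sources used here, and every call has a change of at least 15 points.

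No read numbers accompany the inclusion values or the RPKM values, so the depth per library is unknown and no counting interval was computed. The number of events with a value ranged from 182904 to 207284 per library. Replicates of a group had a median absolute difference between 2.05 and 2.69 percentage points over the tested events, and Pearson's r across events, which are not independent replicates, was between 0.989 and 0.993.

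The design had been laid out for read counts per library, before the data were examined. The files held percentages and authors' test results in their place, so the tests were changed to those the units allow, and the thresholds, contrasts, gene lists and naming rules were kept. For splicing, limma 3.58.1 in R 4.3.3 was fitted to the percentages with 6 group means, with a trended and robust empirical Bayes variance, over all 12 libraries. Of 401633 entries, the 37194 that stand for the first site of an alternative splice site group were left out. Events needed a value in all 12 libraries and a mean between 2% and 98%, a filter chosen after the values had been seen, which left 28980 events in 7019 genes. These were 17096 introns, 6738 cassette exons, of which 195 were microexons of 3 to 27 nt, 3115 alternative 3' splice sites and 2031 alternative 5' splice sites. A change was called at a Benjamini-Hochberg adjusted p under 0.05 with a difference of at least 15 percentage points. Contrasts were knockdown against control (mean of both lines, and each line), rescue against knockdown and against control in each line, and the differences of rescue and of knockdown between the lines.

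For gene expression, the authors' FDR under 0.05 was counted, over the 21541 genes of 54393 that carry a test. A gene was called for the mean of both lines when it passed in both with one sign. The difference between lines was tested by turning each authors' p into a signed z, taking the difference of the z of both lines over its standard deviation, and adjusting by Benjamini-Hochberg. This treats the contrasts of both lines as independent. They share no library, but same-numbered libraries of the lines correlate weakly, as given below. For the differences of rescue and of knockdown, 295 and 269 p-values were under 0.05 where 1077 are given by chance, so small p-values were fewer than a uniform distribution gives. For 20 gene lists fixed before the data were examined, cameraPR of limma compared the signed z of a list with all other genes at a preset correlation of 0.01 between genes. An estimated correlation needs values per library and could not be computed, so 0.05 was tried as a second preset value. The p-values of cameraPR therefore do not measure how far a list as a whole varies between libraries. Beside these, 0 columns of per-sample values were left unused.

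The rescue share is the part of the knockdown change that rescue removed: 100% is a return to the control level and 0% is no return. It was taken from the median over events or genes called in the other line, each signed by its direction, so that the contrast that called the events held no library of the share. The variance behind those calls came from all 12 libraries, so the choice of events was not wholly free of them. Intron lengths were compared between called and other tested introns by the difference of median log10 length, with a two-sided permutation test of 100000 resamples. Microexons among changed exons were compared with Fisher's exact test, two-sided. Sets of events were tested between isoforms with fry of limma, chosen after the data had been seen, which tests whether a set moves one way on balance and does not compare it with other events. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used for lengths and matplotlib 3.10.9 for plots.

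Genes named are Sap30bp first, then the 10 higher and 10 lower with the largest mean log2 fold change among those called, with a mean RPKM of at least 5 and a symbol that is not a predicted gene. The part of this rule on overlap between libraries could not be applied to expression. For splicing they are the 6 higher and 6 lower introns and exons, and the 3 higher and 3 lower alternative splice sites, with the largest change, 1 event per gene. Because few members of a called list passed alone, members with the smallest p in the list's direction are given as values, a choice made after the values were seen. Not every gene or event that these rules name is printed.

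The labels number the replicates 1 and 2 in every group. Within a line, the deviations of same-numbered libraries from their group means correlated across events at 0.15 to 0.31 in all 6 pairs of groups; between lines the 9 correlations were 0.04 to 0.22. By the rule set before the data were examined, a correlation over 0.1 in every pair, the numbers were taken to pair the libraries within a line. The counts of the blocked fit had already been computed when this rule was applied. The labels do not say whether equal numbers share a transfection or a day. The fit reported has no block, so it leaves this pairing out, and it called fewer events for knockdown than the blocked fit. Blocked values stand beside results where they change a call or move a count by over 1.5 times.

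On simulated data with the spread of these libraries, the fit for the mean of both lines recovered 1.5%, 67.2% and 89.4% of changes of 10, 20 and 30 points, with 2.8% false calls. Within the exon-3-containing line the corresponding shares were 0%, 25.4% and 65.2%, with 6.2% false calls. Both sets of rates describe the simulated changes only. They were not estimated for the reported calls, which need a difference of at least 15 percentage points. The simulated changes were placed only in events with a mean percentage in the middle of the scale. The simulated noise was independent between libraries, so it held no correlation between same-numbered libraries. The introns retained more after knockdown started lower, at control medians of 12.1% and 11.4% in the exon-3-lacking and exon-3-containing line. The length test called 4 of 40 simulated sets without a shift and 38 of 40 with a shift of 0.3 on the log10 scale. Alternatives tried were a change of 10 points, a replicate block, leaving out each library, the logit scale, other filters, other choices of events for the rescue share, an RPKM minimum, a combined p over both lines, ranks for the gene lists and a matched background for intron length.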

Results

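RNA from 12 libraries of N2a mouse neuroblastoma cells was profiled for splicing and gene expression. There were 6 groups with 2 replicates each: control, Sap30bp knockdown and rescue, in a line that expresses Sap30bp without exon 3 on doxycycline (exon-3-lacking line) and in a line that expresses Sap30bp with exon 3 (exon-3-containing line). SAP30BP is a nuclear protein that acts with the splicing factor RBM17 on short introns. Inclusion values were available for 182904 to 207284 events per library and the read depth behind them is unknown. Positions are on mm9. Values of intron retention and exon inclusion are means of a group in percent with the SD between replicates, and adjusted p-values for splicing are from limma with Benjamini-Hochberg adjustment.

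The first comparison asked whether the knockdown and the induced isoforms can be seen in Sap30bp itself. In the authors' deposited table, Sap30bp was at 40 RPKM in control, 21.7 after knockdown and 196.5 after rescue in the exon-3-lacking line. In the exon-3-containing line the authors' deposited table gives Sap30bp at 33.6, 18.6 and 141.3 RPKM in the same order. Exon 3 of Sap30bp, 48 nt on chromosome 11 from 115799324 to 115799371, was included in 90.4% ± 0.6 (SD, n = 2) of transcripts in control cells of the exon-3-lacking line. After rescue with the isoform without it, exon 3 inclusion in that line was 8.8% ± 4.1 (SD, n = 2). In the exon-3-containing line, exon 3 inclusion was 94.9% ± 1.2 in control, 96.6% ± 0.3 after knockdown and 99.0% ± 0.3 after rescue (SD, n = 2).

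In the authors' deposited table the log2 fold change of Sap30bp after knockdown was -0.63 (FDR 0.0674) in the exon-3-lacking and -0.60 (FDR 0.0684) in the exon-3-containing line, so the lower level did not pass an FDR of 0.05 in either line. Rescue against knockdown gave log2 fold changes of 2.05 (FDR 6.86e-19) and 1.62 (FDR 7.13e-11) for Sap30bp in the authors' deposited table. The RPKM values of the authors' deposited table give log2 ratios for Sap30bp of -0.88 and -0.85 after knockdown and of 3.18 and 2.93 for rescue against knockdown, so its 2 measures disagree in size. Over 9060 genes with at least 5 RPKM in every group, the median absolute gap between the measures for rescue was 0.07 and 0.03 in the authors' deposited table, where that of Sap30bp was 1.13 and 1.31. The cause of the gap was not tested. Exon 3 inclusion after rescue fell by 62.3 points from knockdown in the exon-3-lacking line (SE 3.0, adjusted p = 9.56e-06). Knockdown alone gave exon 3 inclusion of 71.1% ± 4.5 (SD, n = 2) in that line, a difference from control of -19.3 points (SE 3.0) with an adjusted p of 0.0598. With replicates paired, the adjusted p of this difference was 0.0429. In the authors' deposited table Rbm17, the partner of SAP30BP, was at 102.2 RPKM in control and 117.1 after knockdown in the exon-3-lacking line, and at 104.8 and 115.3 in the exon-3-containing line.

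**Figure D1:**
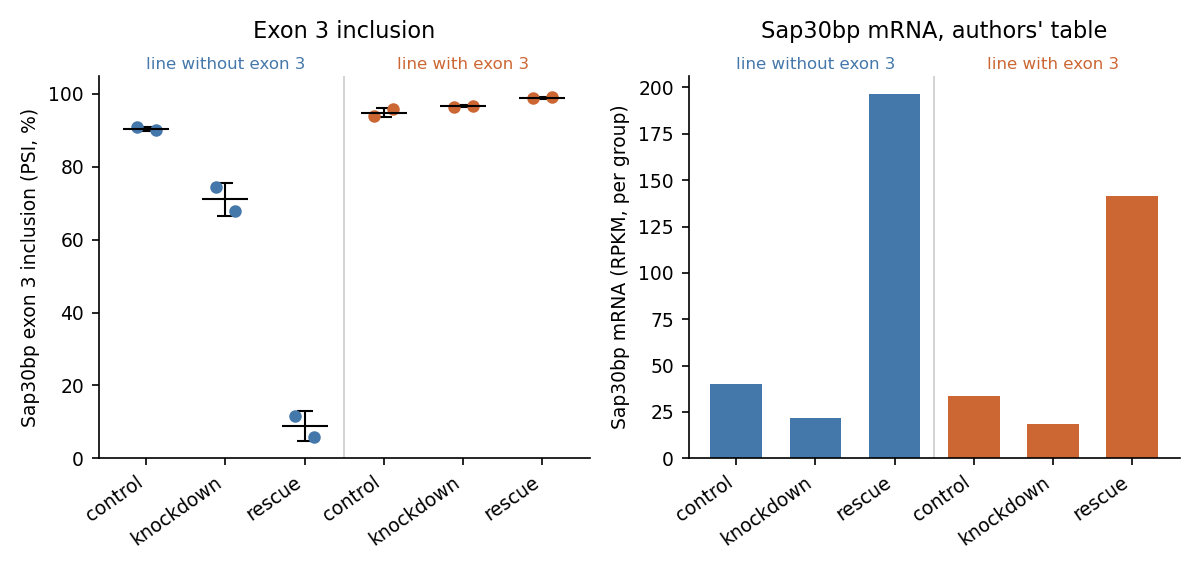
Inclusion of Sap30bp exon 3 in percent per library (left; points are replicates, bars the group mean with SD, n = 2) and Sap30bp mRNA in RPKM per group from the authors' deposited table (right). Exon 3 inclusion was 8.8% in the rescue group of the exon-3-lacking line and 99.0% in that of the exon-3-containing line, with Sap30bp mRNA at 196.5 and 141.3 RPKM.

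The next comparison asked which splicing events depend on Sap30bp, as the mean of knockdown against control in both lines. Introns were retained more: of 272 introns called, 254 in 174 genes were retained more and 18 were retained less. The largest rise was in an intron of 115 nt in Slc26a10 (chromosome 10, 126611225 to 126611339), from 5.8% ± 0.4 to 50.7% ± 11.1 in the exon-3-lacking line and from 2.2% ± 1.2 to 57.6% ± 10.8 in the exon-3-containing line (SD, n = 2). An intron of 141 nt in Pan2, the catalytic subunit of a poly(A) deadenylase, rose by 44.0 points (SE 5.7; chromosome 10, 127751098 to 127751238). Introns of 95 nt in Ilvbl, 77 nt in Mfsd10, 78 nt in Mst1 and 170 nt in H2-Ke6 rose by 43.8, 41.3, 40.5 and 40.2 points (SE 5.7, 4.2, 8.8 and 3.3). Cassette exons moved mostly the other way: 108 of 136 called exons were included less and 28 more.

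Over the 254 introns the median rise was 21.3 points, with quartiles of 17.8 and 26.4, and in 251 of them the replicates of control and knockdown did not overlap in either line. The same libraries called these introns, so this count adds no separate support. Several genes had more than 1 such intron: Dpp7, Dus3l, Plxna3, Rec8 and Skiv2l each had 5, and Cpsf1, a subunit of the mRNA cleavage and polyadenylation machinery, Hirip3, Lime1 and the DNA helicase gene Recql4 each had 4. Introns retained less included those of Tom1l2 (-29.3 points, SE 3.7), Apbb1 (-28.6, SE 5.4), Prpf39, which encodes a U1 snRNP-associated protein (-26.5, SE 3.8), and Gcfc1 (-26.0, SE 3.5). The intron of Prpf39 fell from 85.1% ± 7.2 to 48.4% ± 2.4 in the exon-3-containing line (SD, n = 2). Introns of Mett11d1 and Ddx26b differed by -25.6 and -25.1 points (SE 4.0 and 4.1).

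Among exons included less, a 73 nt exon of Ccnl1, which encodes the splicing-associated cyclin L1, fell from 69.2% ± 3.9 to 28.0% ± 4.4 in the exon-3-lacking line and from 64.4% ± 3.0 to 27.5% ± 0.4 in the exon-3-containing line (SD, n = 2; chromosome 3, 65759126 to 65759198). Exons of Slc9a5, a sodium/proton exchanger, Arhgap33, Rpusd1, Obsl1 and Dpp7 differed by -37.1, -34.7, -34.7, -34.6 and -32.6 points (SE 3.6, 3.7, 4.9, 4.1 and 5.0). Exons included more held a 21 nt microexon of the dynactin subunit gene Dctn4 (28.4 points, SE 3.3). Exons of the tropomyosin gene Tpm1, of Madd and of Hmgxb4 rose by 22.4, 21.8 and 21.2 points (SE 3.8, 5.0 and 2.9), and a 15 nt microexon of Lphn1, an adhesion receptor, rose by 21.3 points (SE 3.0). Of the alternative splice sites, 12 at 3' and 10 at 5' ends were called, among them sites in the p53 regulator gene Mdm4 (24.4 points, SE 5.7), Fam160a2 (20.6, SE 3.5), 2810403A07Rik (20.4, SE 3.5), Fbxo44 (-29.1, SE 4.3), Baz2b (-27.0, SE 4.7) and Sdhaf2, a succinate dehydrogenase assembly factor (-25.2, SE 4.0).

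In all, 430 of 28980 events in 316 genes were called, 290 higher and 140 lower, and 5545 had an unadjusted p under 0.05 where 1449 are given by chance. The count was 168 without replicate 1 of the exon-3-lacking control, 220 without replicate 2 of the exon-3-lacking knockdown and 176 without replicate 1 of the exon-3-containing control; it was 126 with no filter on the mean percentage and 716 at 10 points. Of the 430 events, 393 were also called in either line in the authors' deposited table of splicing events. Introns as a whole moved by less: the median over 17096 introns was 0.82 points and 64.9% were higher. For none of the 20 gene lists did an excess of genes with a retained intron pass its test (Fisher's exact test, two-sided, all 20 adjusted p = 1); the lowest unadjusted p was 0.219, for DNA replication and S phase with 2 of 29 genes. List members with a called intron were Xab2 of the core spliceosome, the replicative polymerase genes Pold1 and Pole, and the neuronal cadherin Celsr3; members with a called exon included Mbnl1 and Ehmt2.

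**Figure D2:**
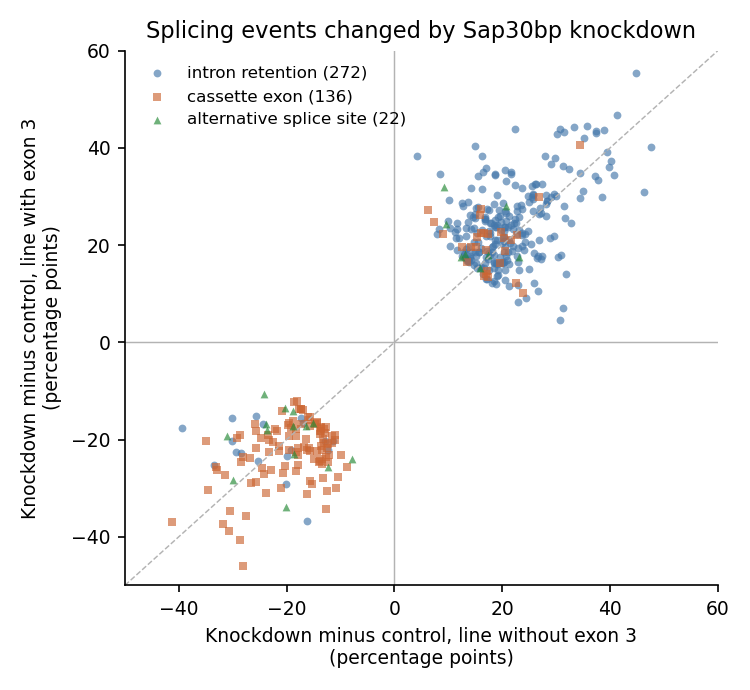
Change in percent spliced in or retained after knockdown in the exon-3-lacking line (horizontal, percentage points) and the exon-3-containing line (vertical), for the 430 events called in the mean of both lines. Each point is 1 event: 272 introns, 136 cassette exons and 22 alternative splice sites, with the dashed line at equal change; introns lie mostly at higher and exons mostly at lower values in both lines.

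Within the exon-3-lacking line, knockdown called 6 events, 5 higher and 1 lower, of which 4 were introns retained more. Within the exon-3-containing line it called 98 events, of which 47 were introns retained more, 3 introns retained less and 34 exons included less. With replicates paired these counts were 63, with 45 introns retained more, and 258, with 154 introns retained more. With values in at least 10 of 12 libraries the first count was 0, and the second was 20 with no filter on the mean percentage and 53 on the logit scale. No event differed in its knockdown effect between the lines by limma (0 of 28980, 927 with an unadjusted p under 0.05; 1 event without replicate 1 of the exon-3-lacking knockdown). The count in the exon-3-lacking line was 206 without replicate 1 of its knockdown, 2 without replicate 1 of the exon-3-containing rescue, and 0 when any 1 of these was left out: the 4 control libraries of both lines, replicate 2 of its knockdown, each replicate of its rescue and replicate 2 of the exon-3-containing rescue. The count in the exon-3-containing line was 0 without either of its controls, 32 without replicate 2 of its knockdown, 15 without either exon-3-lacking control, 47 without replicate 1 of the exon-3-lacking rescue and 59 without replicate 2 of its own rescue. The authors' deposited table of splicing events has 807 calls for knockdown in the exon-3-lacking line, 444 of them introns retained more, and 968 in the exon-3-containing line, 567 of them introns retained more. Both lines share 376 of these calls in the authors' deposited table, 375 of them in one direction and 249 of them introns retained more.

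A further question was which introns depend on Sap30bp by length, given its known part in the splicing of short introns. The 254 introns retained more had a median length of 90.5 nt, with quartiles of 78.0 and 176.75 nt. The other tested introns had a median of 726.5 nt, with quartiles of 221.0 and 1902.75 nt. Of the introns retained more, 78.0% were under 200 nt, against 23.0% of the others. Introns under 100 nt were called in 7.61% of cases (149 of 1958), those from 100 to under 200 nt in 2.33% (49 of 2106), those from 200 to under 500 nt in 1.08% (34 of 3158), those from 500 to under 1000 nt in 0.47% (13 of 2781) and those of 1000 nt and over in 0.13% (9 of 7093). The medians differed by -0.90 on the log10 scale (permutation test, two-sided, p = 1e-05, the smallest that 100000 resamples can give). Against introns matched on host RPKM and control retention, for the 228 called introns (89.8%) whose gene has an RPKM, the difference was -0.81 (permutation p = 1e-05). The 18 introns retained less had a median of 440.0 nt.

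**Figure D3:**
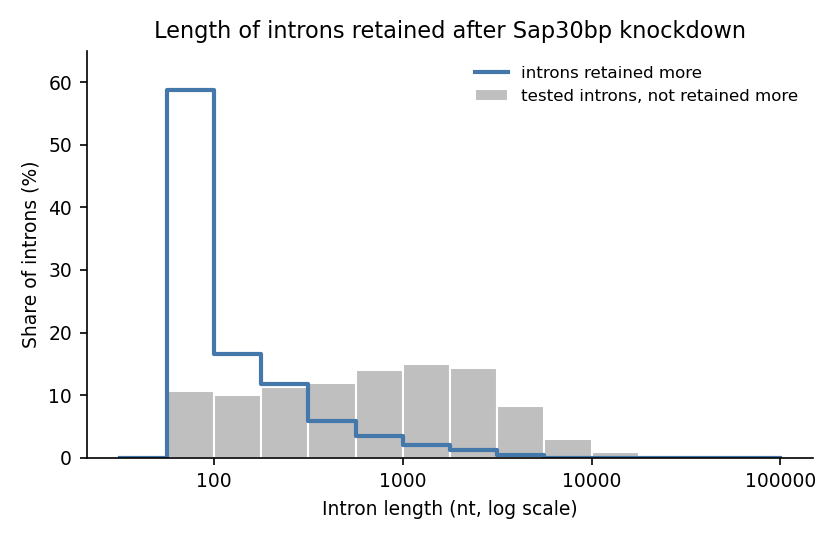
Length in nt on a log scale (horizontal) and share of introns in percent (vertical) for the 254 introns retained more after knockdown (line) and the other tested introns (bars). The bin from 56 to 100 nt holds 58.7% of the introns retained more and 10.7% of the others.

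Microexons were also compared with longer exons. Microexons in Dctn4 and Lphn1 were included more, and 4 others were included less. Of 136 changed exons, 6 (4.41%) were microexons, against 2.86% of the exons without a call. The odds ratio was 1.57 (95% confidence interval 0.56 to 3.57; Fisher's exact test, two-sided, p = 0.292), so no excess of microexons was shown, and the interval leaves room for one.

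The next question was which genes change in expression on knockdown. Genes that rose in both lines in the authors' deposited table were led by Cox6a2, a muscle-type subunit of cytochrome c oxidase (mean log2 fold change 3.35), Lipa, lysosomal acid lipase (2.82), Capn6, a calpain family member (2.74), and Car6, a secreted carbonic anhydrase (2.66). Cox6a2 went from 5.3 to 44.8 RPKM in the exon-3-lacking and from 6.3 to 80.8 RPKM in the exon-3-containing line in the authors' deposited table. Genes that fell in both lines in the authors' deposited table were led by Procr, the endothelial protein C receptor (mean log2 fold change -2.49), Pdzk1ip1 (-2.10), the immediate early response gene Ier3 (-1.89) and Ctla2a (-1.74). Eno2, the neuronal enolase, fell from 196.9 to 82.5 RPKM and from 139.1 to 46.5 RPKM in the authors' deposited table.

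Others that rose in the authors' deposited table were Phactr1 (1.87), the actin-associated Pdlim3 (1.86), Lix1 (1.63), Nrp1, a semaphorin and VEGF receptor (1.34), Slit3, an axon guidance ligand (1.20), and Ppp2r1b, a scaffold subunit of protein phosphatase 2A (1.20). Others that fell in the authors' deposited table were the transporter Abcc3 (-1.55), the tubulin Tuba8 (-1.50), Eno2 (-1.49), the cyclooxygenase Ptgs1 (-1.49), Phlda1 (-1.48) and Tmc8 (-1.46). By the authors' FDR, 339 of 21541 genes passed in both lines with one sign, 154 higher and 185 lower, where independent lists would share 3.6 and 5.4; 0 passed with opposite signs and 4678 had an unadjusted combined p under 0.05. At least a doubling or halving was seen for 242 of the 339. The counts by line were 487 genes in the exon-3-lacking line (241 higher, 246 lower) and 793 in the exon-3-containing line (319 higher, 474 lower). Combining the p-values of both lines called 2287 genes, 913 higher and 1374 lower, which held all 339. The knockdown effect differed between the lines for 2 genes, named after their values were seen: Ccn4, a secreted matricellular protein (log2 fold changes of 0.31 and 1.86 in the exon-3-lacking and exon-3-containing line, adjusted p = 0.00585), and Plcl1 (1.46 and 6.29, adjusted p = 0.00585), which has a mean of 0.455 RPKM. With genes under 1 RPKM left out, 1 gene differed.

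Among the gene lists, the core spliceosome rose on knockdown: 45 of its 50 measured members had a positive mean log2 fold change, with a median of 0.23 and an adjusted p from cameraPR of 7.69e-05, and of 0.0477 at a preset correlation of 0.05 between genes. By the authors' FDR in both lines 0 of the 50 passed, and 4 passed by the combined p of both lines. The values were 0.64 for the tri-snRNP gene Prpf3, 0.58 for Sf3b3, 0.57 for Sf3b4 and 0.41 for Sf3a1, which encode U2 snRNP subunits. SR and hnRNP proteins had a median of 0.16 (37 of 43 higher, adjusted p = 0.0082, and 0.191 at a preset correlation of 0.05), with values of 0.59 for Srsf3, 0.42 for Srsf6, 0.40 for Srsf2 and 0.38 for Hnrnph1. Genes of nonsense-mediated decay and the exon junction had a median of 0.21 (22 of 24 higher, adjusted p = 0.00728, and 0.106 at a preset correlation of 0.05), with values of 0.54 for Acin1, 0.52 for Smg8 and 0.41 for Upf1. NF-kB and immediate early genes had a median of -0.28 (8 of 33 higher, adjusted p = 0.036, and 0.25 at a preset correlation of 0.05): Ier3 fell, with 3 genes called when adjusted over the list alone, and Fosb, Btg2 and Relb had values of -1.15, -0.76 and -0.81.

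Cholesterol synthesis had a median of -0.14 (4 of 24 higher, adjusted p = 0.036, and 0.232 at a preset correlation of 0.05), but its lines differed: -0.43 in the exon-3-lacking line, where Msmo1 fell (-0.72) and 8 genes passed when adjusted over the list alone, and 0.17 in the exon-3-containing line. The other 15 lists were not called in the mean of both lines (adjusted p from 0.0626 to 0.882). Their medians were 0.10 for the SIN3 and HDAC complex, 0.03 for neuronal splicing regulators and -0.23 for p53 targets. The integrated stress response had 0.12, with 1 of 40 members called lower by the authors' FDR in both lines. The unfolded protein response had -0.06 and G2 and M phase -0.11. DNA replication and S phase had 0.11 and DNA damage repair -0.03. Neuronal genes had -0.05, with 2 of 53 members called higher by the same rule, and REST targets and chromatin repression 0.10. The interferon response had -0.16, with 1 of 27 members called higher. Ribosomal proteins had -0.11 and the respiratory chain list -0.09. Markers of other cell types had medians of 0.12 (fibroblast, 10 genes) and 0.06 (glial and immune, 10 genes), with 0 called by the authors' FDR in both lines. By the combined p of both lines, 3 fibroblast markers were lower and 1 glial or immune marker was higher.

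By line, DNA replication and S phase genes had a median of 0.20 on knockdown in the exon-3-lacking line (32 of 39 higher, adjusted p = 0.00202, and 0.0843 at a preset correlation of 0.05). NF-kB and immediate early genes had a median of -0.24 in that line (10 of 33 higher, adjusted p = 0.0452, and 0.237 at a preset correlation of 0.05). Of its members, Ier3 (-1.98) fell and the transcription factor genes Myc (0.74) and Nfkb1 (0.70) rose in the authors' deposited table. In the exon-3-containing line the integrated stress response had a median of 0.15 (25 of 40 higher, adjusted p = 0.0108, and 0.149 at a preset correlation of 0.05). Its members Atf3, a stress-induced transcription factor (1.95), Ppp1r15a, which directs dephosphorylation of eIF2 alpha (0.90), and Sesn2 (0.81) rose, and Pycr1, an enzyme of proline synthesis (-1.09), fell in the authors' deposited table. G2 and M phase genes had a median of -0.15 in that line (6 of 33 higher, adjusted p = 0.0108, and 0.149 at a preset correlation of 0.05).

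**Figure D4:**
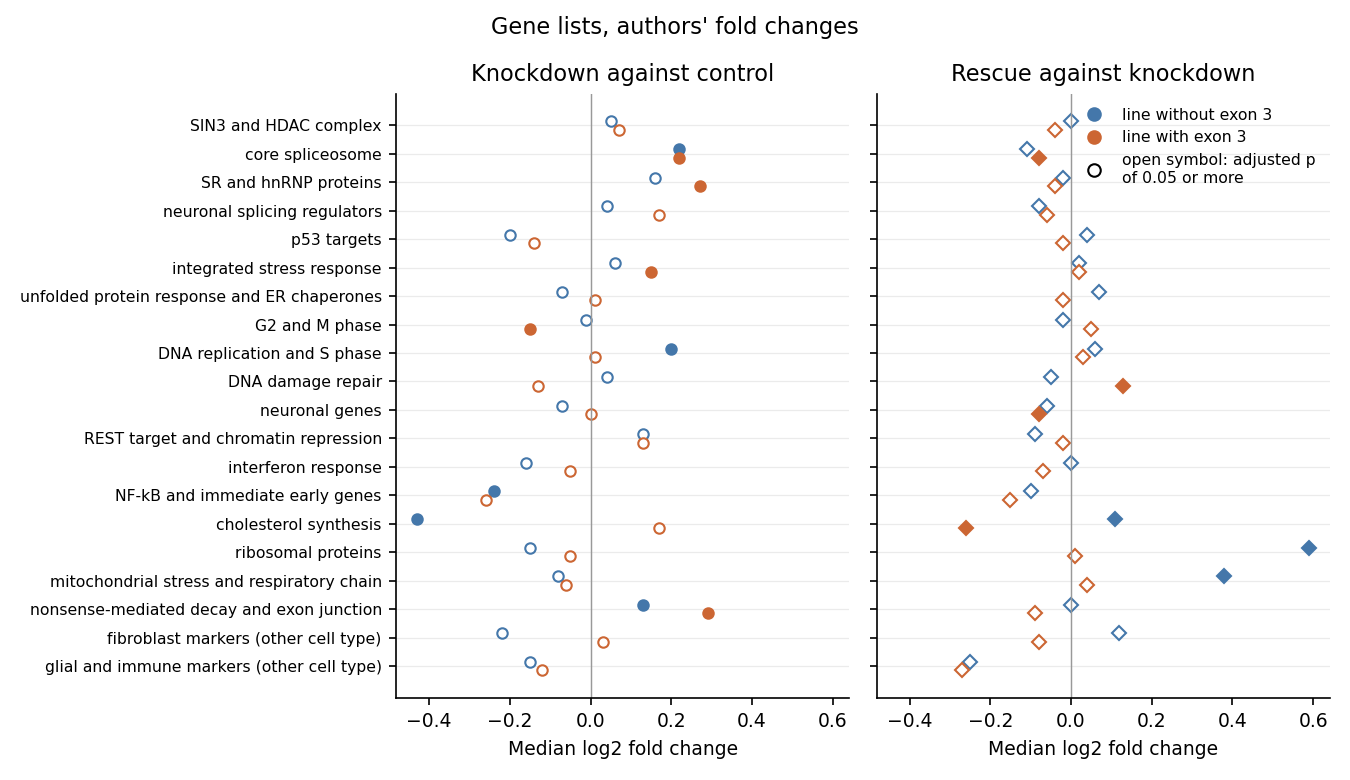
Median log2 fold change from the authors' deposited table (horizontal) for the 20 gene lists (vertical), for knockdown against control (left, circles) and rescue against knockdown (right, diamonds), in the exon-3-lacking line (blue) and the exon-3-containing line (orange). Filled symbols have an adjusted p under 0.05; the ribosomal list lies at 0.59 in the rescue of the exon-3-lacking line and at 0.01 in that of the exon-3-containing line.

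Rescue against knockdown asked how far each isoform brings splicing back. In the exon-3-lacking line, the median retention of the 254 introns was 12.1% ± 2.9 in control, 34.5% ± 6.3 after knockdown and 16.9% ± 3.7 after rescue (SD, n = 2). The exon-3-containing line had 11.4% ± 2.2, 36.4% ± 1.7 and 23.5% ± 1.0 (SD, n = 2). The 108 exons included less had medians of 78.2% ± 4.8, 57.0% ± 7.1 and 67.1% ± 2.1 in the exon-3-lacking line and of 77.3% ± 2.5, 52.6% ± 0.4 and 60.5% ± 1.8 in the exon-3-containing line (SD, n = 2). The intron of Slc26a10 was at 12.0% ± 1.9 after rescue in the exon-3-lacking and at 28.8% ± 14.2 in the exon-3-containing line, and the intron of H2-Ke6 at 45.9% ± 2.7 and 74.3% ± 4.1 (SD, n = 2). From knockdown to rescue the median change of the 254 introns was -16.1 points in the exon-3-lacking line, with 0.4% of introns positive, and -10.9 points in the exon-3-containing line, with 2.4% positive. The 108 exons had median changes of 8.3 and 8.5 points. The exon of Ccnl1 was at 59.2% ± 2.2 and 37.0% ± 2.1 (SD, n = 2), and the intron of Pan2 at 27.3% ± 2.4 and 50.2% ± 1.2 (SD, n = 2). Other exons returned by more points in the exon-3-containing line, such as that of Slc9a5. Its fall on knockdown was also larger there, at -46.0 points against -28.1 in the exon-3-lacking line, so this is no larger share of the fall. The exon went from 40.9% ± 2.2 after knockdown to 52.8% ± 7.1 after rescue in the exon-3-lacking line (SD, n = 2). The exon-3-containing line had 27.7% ± 3.6 and 46.5% ± 4.2 for it (SD, n = 2).

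Event by event, limma called 1 event for rescue against knockdown in the exon-3-lacking line, Sap30bp exon 3 (2485 with an unadjusted p under 0.05), and 0 in the exon-3-containing line (1983 with an unadjusted p under 0.05, against 1449 given by chance). These counts were 23 without replicate 1 of the exon-3-lacking knockdown in the first case; in the second they were 8 and 2 without replicate 1 or 2 of the exon-3-containing knockdown and 1 without either exon-3-lacking rescue. The authors' deposited table of splicing events has 405 calls for rescue against knockdown in the exon-3-lacking line, of which 303 are introns retained less, and 152 in the exon-3-containing line, of which 78 are introns retained less. Against control, limma called 1 event in the exon-3-lacking line, again Sap30bp exon 3 (1618 with an unadjusted p under 0.05), and 0 in the exon-3-containing line (2430 with an unadjusted p under 0.05; 1 event without replicate 2 of its knockdown). The authors' deposited table of splicing events has 251 and 418 calls against control, with 41 and 195 introns retained more.

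The rescue share over events called in the other line was 65.1% in the exon-3-lacking line (98 events; 72.6% and 62.0% in the replicates, SD 7.5). For the exon-3-containing line it was 73.6% (SD 6.2), but on only 6 events, with a mean of 36.1%. Over the 430 events called in the mean of both lines, the shares were 66.4% (SD 17.1) in the exon-3-lacking and 42.9% (SD 2.3) in the exon-3-containing line. Here the control and knockdown libraries of both lines chose the events. The SD of 17.1 holds the offset between replicates and does not measure the spread of paired shares. In that line, replicates 1 and 2 had median signed changes of -1.5 and 1.5 points in control. They were 15.9 and 22.7 points after knockdown, and 3.8 and 8.5 points after rescue. For the introns among the 430 events the shares were 76.4% and 48.1%, and for the exons 44.1% and 33.8%. With events chosen by the paired fit in the other line the shares were 67.7% (258 events) and 49.8% (63 events).

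**Figure D5:**
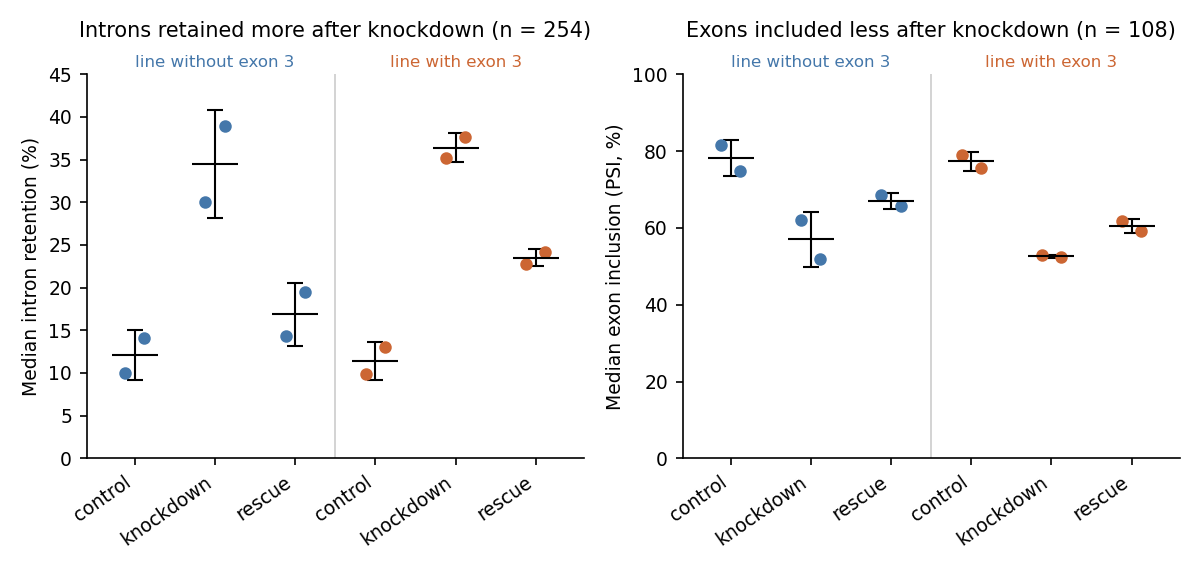
Median retention of the 254 introns retained more (left) and median inclusion of the 108 exons included less (right) after knockdown, in percent, per library; points are replicates and bars the group mean with SD (n = 2). Rescue brings the introns to 16.9% in the exon-3-lacking and 23.5% in the exon-3-containing line, from 34.5% and 36.4% after knockdown.

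Whether the isoforms differ in rescue was tested as the difference of rescue against knockdown between the lines. Only Sap30bp exon 3 itself differed by limma, by 64.8 points (SE 4.3, adjusted p = 0.000261; 1528 events had an unadjusted p under 0.05), and 2 events were called without replicate 1 of the exon-3-lacking knockdown. Over the 254 introns the median difference, exon-3-containing minus exon-3-lacking, was 5.6 points, and 75.2% of introns were positive, which did not pass (adjusted p = 0.342, fry of limma over 8 sets). Without replicate 1 of the exon-3-lacking knockdown it was 9.8 points, with an unadjusted fry value of 0.045, and without replicate 2 of that group it was 1.6 points, with 0.812. It was 2.5 points without replicate 1 of the exon-3-lacking rescue and 3.1 points without replicate 1 of the exon-3-containing knockdown. Leaving out 1 library unbalances the replicate numbers, so these values also hold the offset between replicates 1 and 2. For rescue against control the median difference over these introns was 6.2 points, with 86.2% positive (adjusted p = 0.286, fry of limma). It was 4.1 and 9.6 points without replicate 1 and 2 of the exon-3-lacking rescue. With replicates paired, its unadjusted fry value was 0.0257 against 0.165 without pairing, and the adjusted p over the 8 sets was 0.117. The exons included less differed by 0.1 points between the isoforms against knockdown and by -3.3 points against control (adjusted p = 0.984 and 0.342, fry of limma). The first value was between -2.1 and 3.2 points, without replicate 1 and 2 of the exon-3-lacking knockdown, and the second between -5.9 and -1.2 points, without replicate 1 of the exon-3-lacking and of the exon-3-containing control. The 28 exons included more differed by 6.0 and 7.5 points and the 18 introns retained less by 3.5 and 7.0 points (adjusted p = 0.286, 0.194, 0.194 and 0.194, fry of limma). For introns retained less, a positive difference is a larger return with the exon-3-containing isoform. Their median change from knockdown to rescue was 1.8 points in the exon-3-lacking and 7.2 points in the exon-3-containing line. For these 18 introns the 3.5 points were 6.5 and 2.2 without replicate 2 and 1 of the exon-3-containing knockdown and 5.8 without replicate 2 of the exon-3-lacking rescue, and the 7.0 points were 4.6 without replicate 2 of the exon-3-lacking control. Intron retention as a whole moved too: over all 17096 introns the median change from knockdown to rescue was -1.38 points in the exon-3-lacking and -0.24 in the exon-3-containing line.

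For gene expression, Sap30bp rose on rescue in both lines in the authors' deposited table and was the 1 gene called higher in each. The other 4 genes called in the exon-3-lacking line, named after their values were seen, fell by 8.80 (Zfp935), 8.98 (Gm48275), 2.40 (Gm29609) and 0.93 (Gm49116) on the log2 scale in the authors' deposited table. Of these, Zfp935, a zinc finger gene, has a mean of 0.253 RPKM and Gm48275 of 10.5 RPKM in the authors' deposited table. In the exon-3-containing line Sap30bp was the 1 gene called (286 with an unadjusted p under 0.05, against 1077 given by chance). The genes that changed most on knockdown returned in part or not at all in the authors' deposited table: against control, Cox6a2 was at a log2 fold change of 3.23 after rescue in the exon-3-lacking and 3.45 in the exon-3-containing line, Procr at -1.73 and -2.60, Ier3 at -1.16 and -2.04, and Ctla2a at -0.52 and -1.55. Nrp1 was at 0.26 and 0.96, and Eno2 at -0.87 and -1.73, in the authors' deposited table.

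The rescue share of expression was 29.6% in the exon-3-lacking line over the 793 genes called in the other line (bootstrap SD over genes 1.9), where 624 genes (78.7%) were nearer control. It was 13.2% in the exon-3-containing line over 487 genes (bootstrap SD 2.6), where 346 (71.0%) were nearer control. Replicates were combined before deposit, so these SDs hold no spread between libraries and do not show how surely the lines differ. The means over the same genes gave 19.9% and 10.3%. Against control, 199 genes (116 higher, 83 lower) still differed after rescue in the exon-3-lacking line and 490 (209 higher, 281 lower) in the exon-3-containing line by the authors' FDR; with genes under 1 RPKM left out the first count was 118. Lists that differed from control after rescue in the exon-3-lacking line included DNA replication and S phase (median 0.29, 35 of 39 higher, adjusted p = 7.93e-08) and NF-kB and immediate early genes (-0.37, 9 of 33 higher, adjusted p = 0.000206), where Fosb (-1.56) and Ier3 (-1.16) were lower in the authors' deposited table. Those in the exon-3-containing line included the integrated stress response (0.22, 29 of 40 higher, adjusted p = 0.00198, and 0.0865 at a preset correlation of 0.05), where Atf3 (1.35), Cth (1.11) and Ppp1r15a (0.78) were higher and Pycr1 (-0.77) was lower in the authors' deposited table. NF-kB and immediate early genes differed from control in that line too (-0.38, 9 of 33 higher, adjusted p = 0.00198, and 0.0814 at a preset correlation of 0.05), with Ier3 at -2.04 and Fosb at -1.27 in the authors' deposited table.

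Ribosomal protein genes rose on rescue in the exon-3-lacking line: 57 of 59 were higher, with a median log2 fold change of 0.59 (cameraPR adjusted p = 1.07e-14). Other genes matched to them on transcript length and mean RPKM rose too, with a median of 0.35, so much of the rise is not particular to ribosomal genes. The values were 0.62 for Rps2, 0.91 for Rps14 and 0.75 for Rpl13a in the authors' deposited table, none past an FDR of 0.05. The respiratory chain list had a median of 0.38 (29 of 31 higher, adjusted p = 2.02e-07), with values of 0.62 for Sdhb, 0.53 for Sdhc, 0.55 for Ndufa9 and 0.73 for Ndufa4 in the authors' deposited table. Both lists were called at a preset correlation of 0.05 as well, with adjusted p of 4.87e-06 and 0.000518. These p-values from cameraPR do not measure how far a list median varies between libraries, which is unknown here. Cholesterol synthesis had a median of 0.11 (16 of 24 higher, adjusted p = 0.0479), which was 0.28 at a correlation of 0.05.

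In the exon-3-containing line, cholesterol synthesis fell on rescue: 0 of 24 genes were higher, with a median of -0.26 (adjusted p = 3.5e-14, and 3.44e-08 at a preset correlation of 0.05). The authors' deposited table gives -0.46 for Pmvk, -0.44 for Insig1 and -0.36 for Acat2. DNA damage repair had a median of 0.13 (28 of 31 higher, adjusted p = 0.00113), core spliceosome -0.08 (9 of 50 higher, adjusted p = 0.0102) and neuronal genes -0.08 (16 of 53 higher, adjusted p = 0.0115). At a preset correlation of 0.05 the adjusted p of these were 0.0534, 0.238 and 0.238.

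Between the isoforms, 2 genes differed in rescue, Gm29609 (difference of log2 fold changes 2.86, adjusted p = 0.0218) and Gm48275 (9.04, adjusted p = 0.0126), both predicted genes that were named after their values were seen. By list, the ribosomal genes differed by a median of -0.61 (3 of 59 positive, adjusted p = 4.8e-12), cholesterol synthesis by -0.37 (1 of 24, adjusted p = 3.88e-12), the respiratory chain list by -0.33 (5 of 31, adjusted p = 5.62e-05) and DNA damage repair by 0.17 (23 of 31, adjusted p = 0.0416). The adjusted p at a preset correlation of 0.05 was 4.1e-05, 5.27e-07, 0.00875 and 0.285 in that order. The largest cholesterol differences by p were -0.84 for Pmvk, -0.76 for Insig1, -0.67 for Acat2 and -0.72 for Ebp. The cholesterol list differed between the lines by medians of -0.37 in control, 0.14 after knockdown and -0.26 after rescue. After rescue the lines thus differed in the same direction as in control, and the knockdown groups stood apart.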

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

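The test of a shift over all introns and that of a trend with transcript length and abundance were set before their results were seen; the other tests in this part were chosen only after the result was seen. Every result here is a difference between the 2 lines, which carry different isoforms. Differences of rescue and of knockdown share the 4 knockdown libraries, so they are not independent of each other. A bootstrap SD over introns or genes holds no spread between libraries.

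Over the 254 retained introns, rescue against knockdown differed by a median of 5.6 points between the lines. This smaller return with the exon-3-containing isoform did not pass its test. It was 1.6 and 9.8 points without replicate 2 and 1 of the exon-3-lacking knockdown. The difference was 2.5 without replicate 1 of the exon-3-lacking rescue and 3.1 without replicate 1 of the exon-3-containing knockdown. Leaving out 1 library unbalances the replicate numbers, so these values also hold the offset between replicates 1 and 2. Introns matched on mean percent retained that were not called differed by 3.3 points (bootstrap SD 0.17 over introns), and for rescue against control by 5.4 points where the called introns differed by 6.2 (4.1 and 9.6 without replicate 1 and 2 of the exon-3-lacking rescue), so a shift of intron retention over all introns may account for much of the difference. Matched introns with a median change of 0.5 after knockdown differed by 3.8 and 4.7 points in these comparisons, and 147 of the called introns (57.9%) lay above their matched introns, with a median excess of 1.8 points. A lower level of induced Sap30bp in the exon-3-containing line (log2 fold change -0.57 between the rescue groups in the authors' deposited table, implied SE 0.20) cannot be told apart from a weaker action of the isoform with exon 3, which stays open and untested, since each line has 1 isoform and 1 level of it. The knockdown effect was 2.8 points larger there (bootstrap SD 0.55 over introns), which decides nothing, since a higher level after knockdown would by itself make the change to rescue larger.

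Ribosomal protein genes differed between the isoforms by a median log2 difference of -0.61 and the respiratory chain list by -0.33 in the test of the difference of rescue between the lines. The ribosomal list was higher in the exon-3-containing line in control (median 0.30, adjusted p = 0.00359, and 0.138 at a preset correlation of 0.05) and after knockdown (0.43, adjusted p = 0.000113), and had a median of -0.16 after rescue (adjusted p = 0.392). Genes matched to the ribosomal list on transcript length and mean RPKM differed by -0.37 (bootstrap SD 0.06 over genes), and those matched to the respiratory list by -0.22, so a trend with transcript length and abundance may account for part of both. A shift in the exon-3-lacking knockdown group alone is argued against by the medians. After rescue the ribosomal list was also above control in that line, by a median of 0.44 (bootstrap SD 0.02 over genes), with the knockdown value at -0.15. How far these medians vary between libraries is unknown, since the fold changes are given per group. Both rescue groups received doxycycline. In the exon-3-containing line the ribosomal list had a median of 0.01 after rescue against knockdown and of -0.04 against control. These medians argue against an effect of doxycycline that is the same in both lines. An effect of doxycycline particular to the exon-3-lacking line, or of its induced isoform, was not tested, because no control group received doxycycline.

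Inclusion of Sap30bp exon 3 differed by 64.8 points between the lines in rescue against knockdown, which the cDNAs supply by design, and it was lower after knockdown alone in the exon-3-lacking line. Skipping of the endogenous exon caused by knockdown would lower inclusion in the exon-3-containing line too, where it differed by 1.7 points after knockdown. A leak of the cDNA with exon 3 could hide such skipping there, so this value argues against it only if that leak is absent. A constant leak of the exon-3-lacking cDNA without doxycycline would be 4.9% of the endogenous transcript in control and would leave 14.8% of that transcript after knockdown, with a log2 fold change of Sap30bp of -2.41, where the authors' deposited table has -0.63 (implied SE 0.20) and a log2 ratio of RPKM of -0.88. No other explanation was tested, and skipping of the endogenous exon and a leak that differs between groups stay open.

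The other differences between the lines are given as values. For rescue, cholesterol synthesis differed by a median log2 difference of -0.37 (genes matched on length and RPKM -0.04) and DNA damage repair by 0.17 (adjusted p = 0.0416, and 0.285 at a preset correlation of 0.05). The genes Gm29609 and Gm48275 differed by 2.86 and 9.04 on the log2 scale for rescue. For knockdown, cholesterol synthesis differed by 0.51, with 24 of 24 genes higher in the exon-3-containing line (adjusted p = 1.53e-27, and 6.56e-16 at a preset correlation of 0.05). Both cholesterol differences share the knockdown groups, where the lines differed by a median of 0.14, against -0.37 in control and -0.26 after rescue. SR and hnRNP proteins differed by 0.15 (35 of 43 higher, adjusted p = 0.00198), the integrated stress response by 0.12 (31 of 40, 0.00156), neuronal genes by 0.08 (36 of 53, 0.00614), G2 and M phase by -0.12 (2 of 33, 0.00392), DNA replication and S phase by -0.15 (6 of 39, 0.000793) and DNA damage repair by -0.14 (5 of 31, 0.0216). At a preset correlation of 0.05 these 6 had adjusted p of 0.0752, 0.0752, 0.143, 0.0752, 0.0646 and 0.154. The genes Ccn4 and Plcl1 differed by 1.55 and 4.83 on the log2 scale for knockdown.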

How the results depend on the processing

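Chosen only after the result was seen were the logit scale, the filters on the mean percentage and on 10 of 12 libraries, the RPKM minimum, the combined p, the tests of the gene lists by ranks and at a preset correlation of 0.05, the set tests of the isoforms, and the shares over events of the paired fit and of the authors. With replicates paired, events changed by knockdown were 524 in the mean of both lines (429 shared with the 430), 63 in the exon-3-lacking line and 258 in the exon-3-containing line, and the set test of introns against control between the isoforms kept its 6.2 points and had an unadjusted fry value of 0.0257. With no filter on the mean percentage, where 117021 events are tested, the counts were 126 for knockdown in the mean of both lines, 20 for knockdown in the exon-3-containing line, 5 and 3 for rescue against knockdown in the exon-3-lacking and exon-3-containing line, 1 for rescue against control in the exon-3-containing line and 1 for the difference of knockdown. With values in at least 10 of 12 libraries they were 0 for knockdown in the exon-3-lacking line and 2 each for its rescue against knockdown, its rescue against control and the difference of rescue. On the logit scale they were 53 for knockdown and 1 for rescue against knockdown in the exon-3-containing line, and at 10 points 716 for knockdown in the mean of both lines. The cause of these changes was not tested, apart from the added events in the filters.

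Leaving out 1 library leaves its group with a lone library, assumed to vary like the other groups. It also leaves the replicate numbers unbalanced, and mean intron retention was higher in replicate 2 than in replicate 1 in all 6 groups. The count for knockdown then ranged from 168 (without replicate 1 of the exon-3-lacking control) to 577 in the mean of both lines, from 0 to 206 in the exon-3-lacking line and from 0 to 144 in the exon-3-containing line. Rescue against knockdown ranged from 1 to 23 in the exon-3-lacking line and from 0 to 8 in the exon-3-containing line, rescue against control in the exon-3-containing line from 0 to 1, the difference of rescue from 1 to 2 and the difference of knockdown from 0 to 1. The isoform difference of the introns against knockdown ranged from 1.6 to 9.8 points, without replicate 2 and 1 of the exon-3-lacking knockdown, and against control from 4.1 to 9.6 points. That of the exons included less ranged from -2.1 to 3.2 points around 0.1, with -1.2 without replicate 2 of the exon-3-lacking rescue, -0.5 without replicate 2 of the exon-3-containing knockdown and -1.1 without replicate 1 of the exon-3-containing rescue; against control it ranged from -5.9 to -1.2 points. The cause was not tested. Of 384 values for the 32 results of events that the naming rule gives, with 1 library left out, 348 kept their call, 36 lost it and 0 turned direction. The highest numbers were lost without replicate 1 of the exon-3-containing control (10) and of the exon-3-lacking control (7). With no filter on the mean percentage 16 of the 32 lost their call; 2 did on the logit scale and 2 with values in at least 10 of 12 libraries.

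The rescue share of splicing in the exon-3-containing line, 73.6% on 6 events, was 42.9% over the 430 events, 36.1% as a mean over events, 49.8% with events of the paired fit, 42.4% with the authors' events, and 65.6% and 74.3% with 1 replicate; that of the exon-3-lacking line was 64.8% to 67.7% with other events or the mean and 62.0% and 72.6% with 1 replicate. With the events of the paired fit its replicates gave 83.3% and 53.6%, and with the authors' events 81.6% and 51.1%. These gaps hold the offset between replicates, since each rescue library was set against the group means of control and knockdown. The rescue share of expression was 27.2% over genes called in both lines and 19.9% as a mean over genes in the exon-3-lacking line, and 10.3% as a mean in the exon-3-containing line. The combined p called 2287 genes for knockdown in the mean of both lines, and an RPKM of at least 1 left 118 genes for rescue against control in the exon-3-lacking line and 1 for the difference of knockdown. Ranks called 8 lists for knockdown in place of 5, and a preset correlation of 0.05 called 1 list for knockdown and 1 for rescue against knockdown in the exon-3-containing line. The cause was not tested. The difference in intron length was -0.92 at 10 points and -0.81 against matched introns, and the odds ratio of microexons was 1.70 at 10 points. Of the planned settings, these were not run because no reads or expression values per library were at hand: other scaling, no filter, another count model, the pseudocount, the replicate block and leaving out libraries for genes and gene lists, an estimated correlation, a minimum of 20 reads, weights, a pseudocount of 2 and the quality scores for splicing, lengths and microexons. The depth behind the percentages is unknown, so what it limits was not computed.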

Other observations

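The tests of host genes were set before their result was seen; the tests of the splits of libraries and of introns within genes were chosen only after the result was seen. The lines differed before any knockdown. In control cells neuronal genes were lower in the exon-3-containing line (median log2 difference -0.40, 14 of 53 higher, adjusted p = 9.58e-08, and 0.00152 at a preset correlation of 0.05), with 8 genes called lower. Among these, the authors' deposited table gives -5.35 for Dbh, which makes noradrenaline, -1.86 for Cntn2 and -1.62 for the growth cone gene Gap43. Fibroblast markers were higher there (median 0.72, 8 of 10 higher, adjusted p = 0.000642, and 0.00481 at a preset correlation of 0.05). The authors' deposited table has Acta2, a smooth muscle actin, at 1.1 and 40.9 RPKM in control of the exon-3-lacking and exon-3-containing line, Fn1, fibronectin, at 38 and 173.9 RPKM, and a log2 difference of 1.17 for Pdgfra. Cholesterol synthesis was lower in control of the exon-3-containing line (median -0.37, 2 of 24 higher, adjusted p = 5.54e-06, and 0.00152 at a preset correlation of 0.05), with Lss at -0.85 and Cyp51 at -0.64 in the authors' deposited table, and so was the integrated stress response (-0.22, 8 of 40 higher, adjusted p = 0.000741), with Atf3 at -1.08 in the authors' deposited table. Ribosomal protein genes had a median of 0.30 (53 of 59 higher, adjusted p = 0.00359, and 0.138 at a preset correlation of 0.05). In all, 803 genes differed between the lines in control, 392 higher and 411 lower in the exon-3-containing line, by the authors' FDR.

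Mean intron retention over the 17096 tested introns was higher in replicate 2 than in replicate 1 in all 6 groups. In control, knockdown and rescue of the exon-3-lacking line it was 6.63% and 8.11%, 7.54% and 9.81%, and 5.40% and 7.69%. The exon-3-containing line had 6.24% and 7.71%, 7.71% and 9.81%, and 8.00% and 8.47% in the same order.

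Of the 35 splits of the 8 control and knockdown libraries into 4 and 4, 1 gave as many events as the real split, which is the real one itself: it called 407 events and the highest other split called 1. This excludes chance only if the libraries of both lines can be exchanged, and the lines differ. Of the 35 splits, 18 have 2 libraries of each line per side (highest other 1) and 8 part all 4 pairs of same-numbered control and knockdown libraries (highest other 0), and both are too few for a share under 0.05.

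A hypothesis was that host genes of retained introns have less mRNA after knockdown. For 153 of the 174 host genes with a fold change, the median of the mean log2 fold change was -0.09, against 0.01 for genes matched to them, a difference of -0.10 (permutation p = 7e-04, 10000 matched draws), so such a loss may occur but is small. Of these genes, Tspan17 (-1.17) and Ptprn (-0.96), which encodes a protein of secretory vesicles, fell and Noc3l (0.70) rose in both lines in the authors' deposited table. A second hypothesis was that retained introns cluster in genes: 49 genes held 2 or more of the 254 introns, against a median of 7 and a highest value of 19 in random draws of tested introns (permutation p = 1e-04, the smallest that the draws can give). Neighbouring introns of a gene may share a length class or low reads, which this test does not separate.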
